A study of Triticum aestivum with 36 samples.

How the data were processed

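RNA from the basal and distal parts of wheat flag leaves was hybridised by the authors to the Affymetrix wheat genome array. Per the labels, plants grew in 4-litre pots at 15 to 20 °C with a 16 h photoperiod, stayed 12 h in a mist chamber after treatment, were sampled 48 h later, and gave 5 µg of RNA per array. The deposited table holds 1 linear signal (intensity) per probe set and array, for 61290 probe sets and 36 arrays. The submitters' processing notes name GCOS, but its algorithm and settings are not given in the sources used here. Signals ran from 0.1 to 89865.2, with array medians of 78.7 to 111.6. The mean after trimming 2% at each end was 500.09 to 500.11 on every array, a ratio of 1.00004, so the authors' scaling was kept (the rule allowed up to 1.1).

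Groups were taken from the sample titles and design text: background, line (with or without Lr34), treatment and leaf part, 3 arrays each. The genotype field reads the same for both lines of a background, so the line rests on the words resistant and susceptible in the titles. Resistant was read as with Lr34, which sets the sign of every Lr34 effect. An Lr34 effect here is the difference between the resistant and the susceptible line of a background. Other loci that differ between those lines cannot be told apart from Lr34. The 20 comparisons, their tests and the rule for naming genes were fixed before the data were examined. Of the overlaps between effects, 4 were planned (Lr34 between backgrounds and rust between lines) and the others were added later. Signals were used as log2 of the value plus 16. The 60% of probe sets with the highest mean were tested, 36707 in all, with a lowest mean signal of 51.1. The 111 AFFX control probe sets were left out, and 8 reporter (RPTR) probe sets remained among those tested. A single limma 3.58.1 model in R 4.3.3 held the 12 group means of all 36 arrays (24 residual degrees of freedom, eBayes with an intensity trend, 5.11 prior degrees of freedom). From it 20 comparisons were drawn: with minus without Lr34, rust minus mock, distal minus basal (averaged over the lines), and differences between such effects, called interaction terms. Benjamini-Hochberg adjustment was made over all tested probe sets within each comparison, at 0.05. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6.

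The platform annotation gave 1 gene symbol for 1273 probe sets (771 genes) and none for 60017. Of these genes 770 were found in the RefSeq gene table supplied, and 102 had a readable name or synonym rather than a LOC number. Among tested probe sets 940 were named, for 625 genes, 75 of them readable. For each Lr34, rust or leaf-part effect the named genes are the 10 largest rises and 10 largest falls among called probe sets with 1 gene symbol whose groups did not overlap, 1 probe set per gene. For interactions they are the 5 largest each way, without the overlap rule. Up to 3 called members per direction of each gene list were added, and 2 unnamed probe sets per direction in the Lr34, rust and leaf-part effects. Of 24 gene lists fixed beforehand 11 had a member, with at most 3 genes, so none was tested as a set. Instead 14 groups were made from the gene symbols after these were seen but before any values were compared. Groups with 5 or more genes were tested with limma's camera (inter-gene correlation 0.01, 1 probe set per gene, the brightest) and again with the correlation estimated from the data. Group counts use that brightest probe set, so a gene's own value may come from another.

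Replicate numbers were checked as possible pairs of leaf parts by correlating deviations from group means. In Jupateco all 6 basal and distal pairs exceeded the limit of 0.1 (0.147 to 0.383), and each correlated best with its own number. There, values with a replicate block are given beside the unblocked ones. For swaps of basal and distal, or of their residuals, within leaves, the block correlation was estimated anew on a regular subset of probe sets. In Thatcher 5 of 12 pairs exceeded that limit, with a lowest of -0.137, so the numbers were not taken as pairs. Yet 10 of 12 correlated best with their own number. Susceptible mock basal replicates 2 and 3 each correlated best with the distal part numbered for the other. That is a hint from the data, since the labels do not say whether the numbers pair the leaf parts.

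RNA quality was measured by 3′ to 5′ log2 ratios of control genes with a mean signal of at least 200 at both ends, which 3 of 7 passed. That minimum was chosen after the control signals were seen. These ratios were compared by exact permutation, whose smallest p is 0.1 for 3 against 3. Within groups, arrays correlated at 0.929 to 0.969, and no pair shared more than 0.266% identical values. The first principal component, 38.1% of the variance, separated Jupateco from Thatcher.

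The model was tested on simulated data of 36707 probe sets carrying set changes. For the Lr34 effect in Jupateco distal leaf it found 10.4% of changes of 0.5 log2, 41.8% of 1 and 84.8% of 2. For the rust effect in susceptible distal leaf it found 11.9%, 44.8% and 83.3%, for distal against basal Thatcher 32.8%, 64.2% and 95.5%, and for an interaction 5.97%, 17.9% and 60.6%. With no change set it called 0, and with changes set the false calls were 2, 6, 3 and 3 in the same order. In the real Jupateco distal arrays a split other than the labels called 629 probe sets. The small simulated counts therefore do not bound false calls in the measured data. Alternatives tried were other added constants, other filters, quantile normalization, no trend, replicate blocks, fits of the compared groups alone, and each array left out in turn. Thatcher susceptible rust distal replicate 2 was also left out where its group is not compared. Tallies of 7 or 13 fits without 1 array include that fit, as does the total over comparisons, and it gave the upper end of some ranges.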

Results

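Flag leaves of wheat at mid-anthesis were profiled on 36 Affymetrix wheat genome arrays, 3 for each of 12 groups. Lines with the leaf rust resistance gene Lr34 (here called resistant) and lines without it (susceptible) were compared in the Jupateco and Thatcher backgrounds. All lines were mock inoculated, and the Thatcher lines were also inoculated with Puccinia triticina race MFBL. Every leaf was divided into a basal and a distal part, sampled 48 h after the plants left the mist chamber. Changes below are log2 differences ± standard error between groups of 3 arrays, with p-values adjusted over 36707 probe sets within each comparison. The labels call the replicates biological but do not say whether they were separate plants, so the p-values measure only the spread between these samples. Genes called LOC followed by digits have no function given in the tables used here, and no probe set was named for Lr34 itself. Probe set IDs are written with the sign _ in place of full stops.

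In the basal part of mock-inoculated Jupateco leaves, GLU1A was lower in the line with Lr34 by -2.66 ± 0.46 (adjusted p = 0.00416, n = 3 against 3). GLU1A encodes a beta-glucosidase that releases defensive benzoxazinones from their glucosides. Its mean log2 signal was 6.49 ± 0.26 (SD) in the resistant and 9.15 ± 0.69 in the susceptible line, and 6.03 to 6.56 in the Thatcher basal groups. LOC543018 (-1.49 ± 0.29, adjusted p = 0.0149) and LOC780664 (-0.58 ± 0.12, adjusted p = 0.0348) were also lower, and no named gene was higher. Among probe sets without a gene name, Ta_20930_1_S1_at (5.55) and Ta_11122_1_A1_at (4.42) were highest, and TaAffx_110724_1_S1_at (-5.61) and TaAffx_1074_1_S1_at (-5.28) lowest. In all, 58 probe sets differed, 26 higher and 32 lower (limma, adjusted p), against 1946 at an unadjusted p of 0.05. All 3 named genes lost their call in at least 1 fit that left out an array, and a fit of the 2 groups alone called 9 probe sets.

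In the distal part of the same Jupateco leaves, LOC542799 was higher with Lr34 by 5.18 ± 0.50 (adjusted p = 1.38e-07, n = 3 against 3) and LOC542888 by 4.13 ± 0.45 (adjusted p = 1.17e-06). LEA1, a late embryogenesis abundant protein of the kind made under drought and abscisic acid, was higher by 2.29 ± 0.54 (adjusted p = 0.0378). Its mean log2 signal was 8.55 ± 0.45 (SD) against 6.26 ± 0.30. LOC606323 (2.33), LOC780599 (1.43), LOC543245 (1.21), LOC100037645 (1.1), LOC100037531 (1.08), LOC543255 (1.03) and LOC542848 (0.83) were the other rises among the 10 that the naming rule allows. LOC542781 (2.42) was called too, but its groups overlapped. GLU1A was again lower (-3.60 ± 0.46, adjusted p = 2.35e-05), with LOC543018 (-1.71 ± 0.29, adjusted p = 0.00139) and LOC543086 (-0.63). The 4 unnamed probe sets that led the basal comparison led here too: Ta_20930_1_S1_at (5.75), Ta_11122_1_A1_at (4.79), TaAffx_110724_1_S1_at (-6.03) and TaAffx_1074_1_S1_at (-5.73). Of the 13 named genes 6 kept their call in every fit that left out 1 array, and LEA1 in 2 of 7.

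In the Jupateco distal part 294 probe sets differed, 207 higher and 87 lower (limma, adjusted p); 4448 did so at an unadjusted p of 0.05. The 9 photosynthesis and chloroplast genes had a median of -0.21 as a group, and none of them was called alone (camera, adjusted p = 0.0157). That group call was lost with adjusted p = 0.379 with an estimated correlation, and with 0.605 after quantile normalization. Of the 2 cold, drought and abscisic acid induced genes listed beforehand, LEA1 was called over all genes and 2 were when adjusted over the list alone. Dependence on single arrays was large: 165 probe sets differed without resistant distal replicate 3, 146 without susceptible distal replicate 1, 1161 without susceptible distal replicate 2 and 145 without susceptible distal replicate 3. A fit of the 2 groups alone called 12. The 3′ to 5′ log2 ratio of the glucose-6-phosphate dehydrogenase control was higher by 0.58 in the resistant line (exact p = 0.1, the smallest possible with 3 against 3).

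In the basal part of mock-inoculated Thatcher leaves, LOC542869 was lower with Lr34 by -5.81 ± 0.27 (adjusted p = 1.63e-15, n = 3 against 3). Its mean log2 signal was 6.26 ± 0.17 (SD) in the resistant and 12.07 ± 0.19 in the susceptible line, whereas the Jupateco basal groups with and without Lr34 read 12.59 and 12.62. LOC780602 (-3.78 ± 0.39, adjusted p = 1.82e-07) and LOC542908 (-2.41 ± 0.37, adjusted p = 0.000171) were lower as well. PEAMT1, a phosphoethanolamine methyltransferase of choline synthesis, was lower by -1.36 ± 0.29 (adjusted p = 0.0129), and SAHH, an S-adenosylhomocysteine hydrolase, by -0.70 ± 0.17 (adjusted p = 0.0468). Another probe set of SAHH, Ta_1258_1_S1_a_at, read -0.47 without passing the test. LOC606366 (-1.36) and LOC542778 (-0.89) were the other lower genes. LOC100125710 was the highest named gene (1.87 ± 0.24, adjusted p = 1.14e-05), followed by LOC100037524 (0.84), LOC543379 (0.54), LOC780601 (0.49) and LOC100049038 (0.41). Unnamed probe sets Ta_13874_1_S1_at (4.93) and Ta_25839_1_A1_a_at (4.28) were highest, and Ta_28123_1_S1_at (-7.27) and Ta_4137_1_S1_at (-6.92) lowest. In all, 300 probe sets differed, 96 higher and 204 lower (limma, adjusted p), and 3168 at an unadjusted p of 0.05. Of 12 named genes 6 kept their call whichever array was left out, and SAHH in 1 of 7 such fits. The count was 186 without resistant mock basal replicate 2, 196 without susceptible mock basal replicate 1, and 145 in a fit of the 2 groups alone.

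In the distal part of mock-inoculated Thatcher leaves, LOC542799 was higher with Lr34 by 7.03 ± 0.50 (adjusted p = 4.2e-11, n = 3 against 3), LEA1 by 4.96 ± 0.54 (adjusted p = 2.77e-07) and LOC542888 by 4.86 ± 0.45 (adjusted p = 1.03e-08). LEA1 averaged 10.42 ± 0.25 (SD) in the resistant and 5.46 ± 1.19 in the susceptible line. LOC542781 (3.31), LOC543150 (3.07), LOC543369 (2.68), LOC100125738 (2.51), LOC543196 (2.49), LOC100125736 (2.25) and LOC780599 (2.06) followed. LOC542869 was again the lowest named gene (-6.44 ± 0.27, adjusted p = 9.89e-17), then LOC780602 (-2.80), LOC542908 (-2.11), LOC543145 (-1.97), LOC543340 (-1.49) and LOC606366 (-1.09). Unnamed probe sets Ta_2638_1_S1_at (6.78) and Ta_11025_1_A1_at (5.80) were among the highest, and Ta_4137_1_S1_at (-7.72) and TaAffx_103568_1_S1_at (-7.12) the lowest. Leaving out any 1 array kept 13 of the 16 named genes.

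In this Thatcher distal comparison 690 probe sets differed, 524 higher and 166 lower (limma, adjusted p), and 3728 did so at an unadjusted p of 0.05. The 6 starch, fructan and sugar genes had a median of 0.23 with none called alone (camera, adjusted p = 0.0295). The group lost its call with adjusted p = 0.0665 with an estimated correlation, and with 0.125 over all probe sets. The fructan exohydrolases 1-FEH and 6-FEH, listed beforehand, were both higher when adjusted over the list alone and neither was over all genes. LEA1 was the single call among 2 listed cold, drought and abscisic acid genes, both over all genes and adjusted over the list alone. The ubiquitin control 3′ to 5′ log2 ratio differed by -0.07 (exact p = 0.1, the smallest possible).

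After rust inoculation, the basal part of resistant Thatcher leaves carried more LOC543233 (3.45 ± 0.84, adjusted p = 0.0352, n = 3 against 3) and more LTP3, a lipid transfer protein (1.04 ± 0.26, adjusted p = 0.0391), than susceptible leaves. LOC100125710 (1.78), LOC543004 (1.23), LOC778422 (1.13), LOC100037524 (1.06), LOC542794 (1.04), LOC100037539 (0.98), LOC780661 (0.81) and LOC543230 (0.67) were higher too. LOC542888, which was higher with Lr34 in distal leaf, was lower here (-1.85 ± 0.45, adjusted p = 0.0351), but kept that call in only 1 of 7 fits without 1 array and in 6 of 9 alternatives. The lowest was LOC542869 (-6.13 ± 0.27, adjusted p = 5.03e-16), with LOC780602 (-2.28), LOC543340 (-1.89), LOC542908 (-1.83), LOC100049041 (-1.62), LOC543267 (-1.23), LOC542999 (-1.18), LOC542993 (-0.98) and LOC542992 (-0.83). Unnamed Ta_13874_1_S1_at (4.68) and Ta_25839_1_A1_a_at (4.35) were highest and Ta_4137_1_S1_at (-7.33) and Ta_28123_1_S1_at (-6.51) lowest. Of the 20 named genes 9 held whichever array was left out, LOC543233 in 2 and LTP3 in 3 of 7 such fits.

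That rust basal comparison of the Thatcher lines called 406 probe sets, 141 higher and 265 lower (limma, adjusted p), and 4119 passed an unadjusted p of 0.05. Groups without any member called alone were higher: photosynthesis and chloroplast (9 genes, median 0.23, camera adjusted p = 0.0124), redox and detoxification (5 genes, median 0.19, 0.032) and starch, fructan and sugar (6 genes, median 0.28, 0.0272). None held: adjusted p = 0.305, 0.12 and 0.105 with an estimated correlation, and 0.283, 0.103 and 0.0636 after quantile normalization. LTP3 was called both over all genes and adjusted over its list alone. The count was 261 without resistant rust basal replicate 2, 214 without resistant rust basal replicate 3, 154 without susceptible rust basal replicate 1 and 249 without susceptible rust basal replicate 3.

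In rust-inoculated distal leaf, LOC542799 was higher in resistant than in susceptible Thatcher by 6.52 ± 0.50 (adjusted p = 1.19e-10, n = 3 against 3), LEA1 by 5.02 ± 0.54 (adjusted p = 9.7e-08) and LOC542888 by 3.97 ± 0.45 (adjusted p = 2.25e-07). Rab15, an abscisic acid responsive dehydrin, was higher by 2.35 ± 0.66 (adjusted p = 0.0226), averaging 8.08 ± 0.08 (SD) against 5.73 ± 0.86. LOC543233 (3.58), LOC543150 (3.50), LOC542781 (3.30), LOC100125736 (3.23), LOC543196 (2.98), LOC543338 (2.90) and LOC543383 (2.65) were the next highest. Fructan breakdown genes were higher, 6-FEH by 1.13 ± 0.29 (adjusted p = 0.0116) and 1-FEH by 0.80 ± 0.23 (adjusted p = 0.0283), as was the zeta glutathione transferase GSTZ1 (0.52 ± 0.13, adjusted p = 0.00953). Of 3 probe sets for GSTZ1, Ta_237_1_S1_at did not differ (-0.01). The tubulins tubb1 (0.86, adjusted p = 0.0499) and TUBA (0.43, adjusted p = 0.0305) and the protein repair gene PIMT (0.63, adjusted p = 0.0388) were also higher, but weakly so. In 6 fits without 1 array, tubb1 kept its call in 0, TUBA and Rab15 in 2, PIMT and 1-FEH in 1, and tubb1 in 4 of 9 alternatives.

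Lower with Lr34 in rust-inoculated distal leaf were LOC542869 (-6.09 ± 0.27, adjusted p = 6.04e-16), LOC780602 (-2.61), LOC542908 (-1.80), LOC100049041 (-1.70), LOC543340 (-1.56), LOC606390 (-1.44), LOC543008 (-1.20), LOC606346 (-0.98) and LOC543090 (-0.93). The histone gene wcH2B-8 was lower on probe set Ta_7378_21_S1_at (-1.86 ± 0.43, adjusted p = 0.00489), but its other probe sets read -0.66 to 0.05 and did not pass. Trx-M, a chloroplast thioredoxin (-0.49 ± 0.12, adjusted p = 0.00731), rbcl (-0.62, adjusted p = 0.043), ALP (-0.37) and the initiation factor Eif4B (-0.29, adjusted p = 0.0368) were lower. Without 1 array, Eif4B kept its call in 0 of 6 fits and rbcl and ALP in 3. Of the 31 named genes 16 kept it in all. In all, 3166 probe sets differed, 1783 higher and 1383 lower (limma, adjusted p), and 7826 at an unadjusted p of 0.05. Unnamed TaAffx_79139_1_S1_at (7.63) and Ta_2638_1_S1_at (7.32) were highest, and Ta_4137_1_S1_at (-7.61) and Ta_28123_1_S1_at (-7.08) lowest. Both listed cold, drought and abscisic acid genes and both listed fructan genes were called over all genes and adjusted over the list alone. The count fell to 1771 without resistant rust distal replicate 2 and to 1664 without susceptible rust distal replicate 2. The sucrose synthase 3′ to 5′ log2 ratio was lower by -1.01 in the resistant line (exact p = 0.1, the smallest possible).

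Rust inoculation raised LOC100125708 in the basal part of resistant Thatcher leaves by 4.13 ± 0.86 (adjusted p = 0.00813, n = 3 against 3), LOC606323 by 3.21 ± 0.57 (adjusted p = 0.00209) and LOC543201 by 2.81 (adjusted p = 0.0103). LOC542830 (1.98), LOC543297 (1.89), LOC543143 (1.56), LOC606366 (1.3), LOC778397 (0.56), LOC542890 (0.55) and LOC543101 (0.54) also rose. LOC543123 fell most among named genes (-2.58 ± 0.50, adjusted p = 0.00476), followed by LOC542855 (-1.91), LOC606326 (-1.87), LOC100037599 (-1.77), LOC778422 (-1.17), LOC606346 (-1.09), LOC100049041 (-0.91), LOC100037539 (-0.81) and LOC542992 (-0.77). LOC542869 passed on probe set Ta_262_1_S1_x_at (-0.98, adjusted p = 0.0487), but Ta_262_1_S1_at read 0.28. Unnamed TaAffx_108353_1_S1_at (4.69) and TaAffx_116570_1_S1_s_at (4.44) rose most and Ta_29534_1_S1_x_at (-3.61) and Ta_29534_1_S1_at (-3.59) fell most.

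This basal response of the resistant line took in 787 probe sets, 316 higher and 471 lower (limma, adjusted p), and 5383 at an unadjusted p of 0.05. As groups, the 9 photosynthesis and chloroplast genes (median -0.16) and the 7 tubulins and profilin (median -0.27) were lower, each with a camera adjusted p = 0.0408 and no member called alone. Neither held, with adjusted p = 0.611 and 0.466 with an estimated correlation. Only 5 of 20 named genes kept their call whichever array was left out. The count was 280, 473 and 476 without resistant rust basal replicates 1, 2 and 3, and 224 and 392 without resistant mock basal replicates 1 and 3.

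In the distal part of resistant Thatcher leaves, rust raised LOC100125708 by 5.39 ± 0.86 (adjusted p = 3.84e-05, n = 3 against 3), from a mean log2 signal of 8.66 ± 0.88 (SD) to 14.05 ± 0.20. Named genes of known function also rose. They were XIP-I, a xylanase inhibitor (1.81 ± 0.39, adjusted p = 0.00119), COMT1, a caffeic acid methyltransferase of lignin synthesis (1.11 ± 0.28, adjusted p = 0.00599), and DMAS1, which makes the iron chelator deoxymugineic acid (0.98 ± 0.19, adjusted p = 0.000398). LOC543287 (3.88), LOC543317 (3.86), LOC542887 (3.20), LOC543201 (2.96), LOC778410 (2.77), LOC542830 (2.69), LOC606366 (2.60), LOC780640 (2.57) and LOC543342 (2.47) were other large rises. LOC606390 fell most (-2.48 ± 0.36, adjusted p = 1.05e-05), then LOC100037553 (-2.23). GAPN, a cytosolic glyceraldehyde-3-phosphate dehydrogenase that forms NADPH, fell by 1.73 ± 0.23 (adjusted p = 2.75e-06). PEAMT1 (-1.58 ± 0.29, adjusted p = 0.000218), LTP3 (-1.22 ± 0.26, adjusted p = 0.000967) and LMW-GS (-1.64) fell as well. The histone wcH2B-8 fell by 1.5 on its brightest probe set, and other falls were AGP-S (-0.39, adjusted p = 0.0022), AGA.1 (-0.71, adjusted p = 0.000111) and TEF1 (-0.23). LOC606346, LOC543256, LOC100049023, LOC542880, LOC543355, LOC543499 and LOC100037599 completed the largest falls. Of 38 named genes 32 kept their call in all fits without 1 array, LMW-GS in 1 of 7 and wcH2B-8 and TEF1 in 2.

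Photosynthesis genes made up the clearest group in that comparison: 8 of 9 fell, with a median of -0.80 (camera, adjusted p = 2.38e-07), though adjusted p = 0.0968 with an estimated correlation. PsbP and PsbO, subunits of the oxygen-evolving complex, fell by 0.70 ± 0.15 (adjusted p = 0.000997) and 0.56 ± 0.13 (adjusted p = 0.00253). The chloroplast ribosomal protein RPL9 (-1.57 ± 0.21, adjusted p = 3.6e-06) and the peroxiredoxin Prx1 (-1.31 ± 0.21, adjusted p = 3.55e-05) fell with petC, PRK, FBP and Trx-M. Probe sets for rbcl, the large subunit of Rubisco, differed: TaAffx_128414_181_S1_at fell by 1.32 (adjusted p = 1.51e-05), while the brightest, Ta_24976_1_S1_x_at, read -0.06 and was not called. In the redox group 3 of 5 genes fell, namely CAT1 (-0.57 ± 0.10, adjusted p = 0.000183), Prx1 and the glyoxalase lgul (-1.54 ± 0.22, adjusted p = 9.47e-06). That group had a camera adjusted p = 0.035, and adjusted p = 0.0968 with an estimated correlation. Phosphoglycerate kinase Pgk-1 fell by 0.95 ± 0.15 (adjusted p = 3.37e-05).

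Rust changed 6427 probe sets in the resistant distal part, 2457 higher and 3970 lower (limma, adjusted p), and 10668 at an unadjusted p of 0.05. Unnamed TaAffx_108353_1_S1_at (6.83) and Ta_14903_1_S1_at (6.33) rose most, and Ta_3979_1_S1_at (-4.66) and Ta_15927_1_S1_at (-3.47) fell most. The defence group had 1 member higher, XIP-I, and 1 lower, LTP3, out of 8 (camera, adjusted p = 0.238). Both photosynthesis genes listed beforehand, PsbO and PsbP, fell over all genes and adjusted over the list alone. PR5, a thaumatin-like pathogenesis-related protein, rose when adjusted over its list alone (1.12 log2) but not over all genes (adjusted p = 0.139). The glucose-6-phosphate dehydrogenase 3′ to 5′ log2 ratio was higher by 0.24 after rust (exact p = 0.1, the smallest possible).

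In the basal part of susceptible Thatcher leaves, rust raised LOC542888 by 2.70 ± 0.45 (adjusted p = 0.000501, n = 3 against 3), from 5.91 ± 0.35 (SD) to 8.62 ± 0.23. XIP-I (1.23 ± 0.39, adjusted p = 0.0473) and DMAS1 (0.81 ± 0.19, adjusted p = 0.00866) rose, with LOC542876 (2.05), LOC543453 (1.48), LOC543430 (1.39), LOC543297 (1.24), LOC542957 (1.21), LOC543141 (1.12), LOC100037645 (1.09) and LOC543268 (0.92). LOC778422 fell by 2.39 ± 0.26 (adjusted p = 3.51e-06). LTP3 fell by 2.00 ± 0.58 (adjusted p = 0.0295) on probe set Ta_1282_4_S1_at and by 1.91 on the brighter Ta_1282_1_S1_x_at. PEAMT1 (-1.46 ± 0.29, adjusted p = 0.0024), lgul (-1.07 ± 0.22, adjusted p = 0.00338), tubb2 (-1.07 ± 0.25, adjusted p = 0.00717) and raftin1b (-1.24 ± 0.30, adjusted p = 0.0105) fell. So did RPL9 (-0.66, adjusted p = 0.0495), Prx1 (-0.62), LOC542846 (-2.08), LOC543421 (-2.03), LOC543404 (-1.96), LOC100037539 (-1.82), LOC543256 (-1.74), LOC542855 (-1.58) and LOC543357 (-1.40). GSTZ1 (-0.75) and rbcl (-1.03) fell on Ta_237_1_S1_at and TaAffx_128414_72_S1_at, while their brightest probe sets read -0.10 and -0.13 without passing. Of 28 named genes 9 kept their call whichever array was left out. XIP-I did in 2, rbcl in 1 and LTP3, Prx1 and RPL9 in 3 of 7 such fits. Unnamed Ta_22693_2_A1_at (4.29) and Ta_5248_1_S1_x_at (3.50) rose most and Ta_5776_1_S1_at (-3.10) and Ta_22094_1_S1_at (-3.08) fell most.

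The basal response of the susceptible line covered 2848 probe sets, 1177 higher and 1671 lower (limma, adjusted p), and 7959 at an unadjusted p of 0.05. Of the 9 photosynthesis and chloroplast genes 3 fell, RPL9, FBP and Trx-M, with a group median of -0.32 (camera, adjusted p = 0.00552, and adjusted p = 0.43 with an estimated correlation). Among 8 defence genes 1 rose and 1 fell (camera, adjusted p = 0.908), and among 5 redox genes 1 fell (camera, adjusted p = 0.0645). Leaving out 1 array gave 976 without susceptible rust basal replicate 1, 1419 without susceptible rust basal replicate 3, 1594 without susceptible mock basal replicate 1 and 836 without susceptible mock basal replicate 3.

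In the distal part of susceptible Thatcher leaves, rust raised PR5 by 1.56 ± 0.51 (adjusted p = 0.0326, n = 3 against 3), from 13.62 ± 0.87 (SD) to 15.18 ± 0.15. That call held in all 9 alternatives but in only 1 of 6 fits without 1 array. XIP-I (1.79 ± 0.39, adjusted p = 0.00194), COMT1 (0.97 ± 0.28, adjusted p = 0.0167) and DMAS1 (0.97 ± 0.19, adjusted p = 0.000766) rose, as did TPC1, a vacuolar cation channel (0.44 ± 0.14, adjusted p = 0.0214). LOC543201 (2.91 ± 0.60, adjusted p = 0.00123), LOC780640 (2.78), LOC100125708 (2.62), LOC542887 (2.58), LOC100125738 (2.43), LOC543197 (2.42), LOC606308 (2.29), LOC606323 (2.14), LOC543342 (2.09) and LOC100037560 (1.96) were the largest rises. LOC543145 fell by 2.53 ± 0.51 (adjusted p = 0.000909). Further falls were LOC606348 (-2.20), LOC100037562 (-2.10), LOC543357 (-1.98), LOC543256 (-1.96), LOC542846 (-1.88), LOC543421 (-1.83), LOC543383 (-1.82) and LOC542817 (-1.78). LTP3 (-1.70 ± 0.26, adjusted p = 6.05e-05), PEAMT1 (-1.28 ± 0.29, adjusted p = 0.00266) and the tubulin Tubb5 (-1.14) fell too. GSTZ1 fell by 0.60 on Ta_237_1_S1_at, but its other probe sets read -0.26 and 0.18 without passing. Of 36 named genes 19 kept their call whichever array was left out. LOC100125708 and LOC542887 did in 1 of 6 such fits, and TPC1, PsbO, AGA.1, GSTZ1, rbcl and Tubb5 in 2. Unnamed Ta_5810_1_S1_at (4.57) and TaAffx_54541_1_S1_at (4.05) rose most and TaAffx_49891_1_S1_at (-4.46) and Ta_22094_1_S1_at (-3.35) fell most.

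Photosynthesis genes fell in the susceptible distal part as well, 8 of 9 with a median of -0.48 (camera, adjusted p = 3.65e-05, and adjusted p = 0.2 with an estimated correlation). PsbP fell by 0.92 ± 0.15 (adjusted p = 0.000121), RPL9 by 1.1 ± 0.21 (adjusted p = 0.000608), Prx1 by 0.86 and PsbO by 0.38 (adjusted p = 0.0384). Among 5 redox genes 3 fell, lgul (-1.19 ± 0.22, adjusted p = 0.000473), Prx1 and CAT1, with a group median of -0.70 (camera, adjusted p = 0.0128, and adjusted p = 0.0995 with an estimated correlation). Pgk-1 (-0.65) and AGA.1 (-0.42) fell, and rbcl fell by 0.95 on TaAffx_128414_72_S1_at but not on its brightest probe set (-0.20). Rust changed 6739 probe sets here, 2748 higher and 3991 lower (limma, adjusted p), and 11289 at an unadjusted p of 0.05. The median of all probe sets moved by -0.11, and the count was 3803 without susceptible mock distal replicate 2. PsbO and PsbP, listed beforehand, fell over all genes and adjusted over the list alone, and PR5 rose in both counts. The 3′ to 5′ log2 ratios of sucrose synthase and glucose-6-phosphate dehydrogenase were higher after rust by 1.22 and 0.85 (exact p = 0.1 each, the smallest possible).

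**Figure D1:**
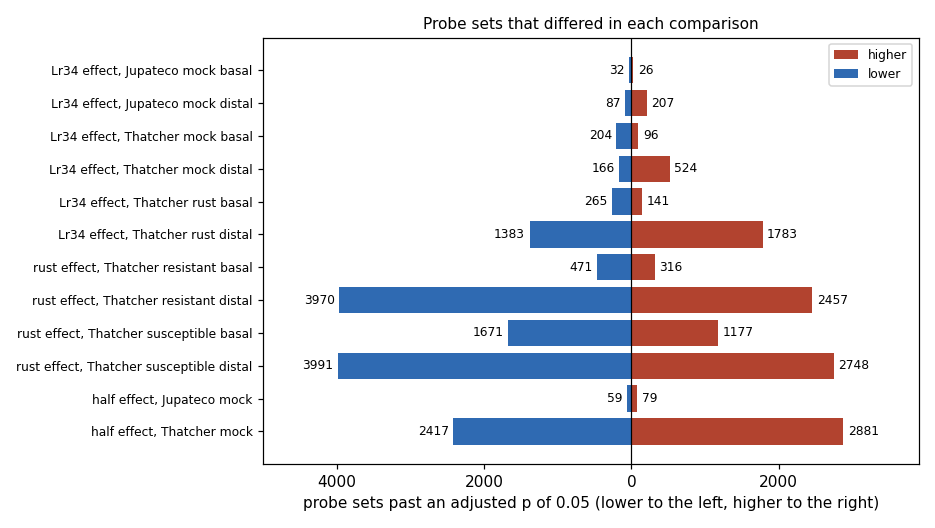
Number of probe sets higher and lower in each comparison (limma, adjusted p).

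**Figure D2:**
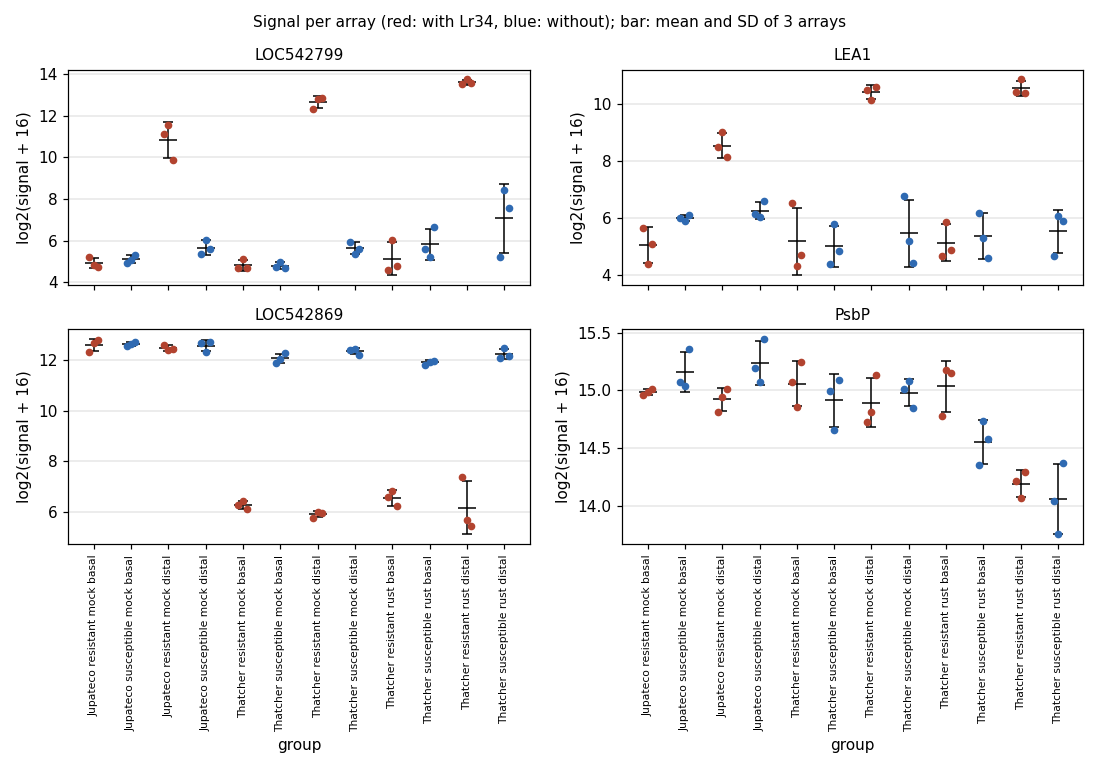
Log2 signal of LOC542799, LEA1, LOC542869 and PsbP on every array, with mean and SD of 3 arrays per group.

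Few probe sets were called as responding differently to rust in the Thatcher lines. Many differences could be missed: in simulated data an interaction term found 17.9% of changes of 1 log2 and 60.6% of 2. LOC606366 was the single named gene in the basal part, with a change larger in the resistant line by 1.58 ± 0.30 (adjusted p = 0.0407), on probe set Ta_3828_3_A1_a_at. It rose by 1.15 in resistant leaves and read -0.43 in susceptible ones, and passed in 4 of 13 fits without 1 array. In total 13 probe sets differed in basal leaf, 5 higher and 8 lower (interaction term, adjusted p), and 27 in distal leaf, 18 higher and 9 lower, none with a gene name. With quantile normalization the distal count was 33, as 17 higher and 16 lower, and the basal count 21. The distal count was 57 with 64 added to the signal and 42 with the top 40% of probe sets, and the basal count 27 in a fit of these groups alone. The basal count was 8 without resistant rust basal replicate 2, 7 without resistant mock basal replicate 1, 7 without susceptible rust basal replicate 1 and 8 without susceptible mock basal replicate 2. The distal count was 11 and 8 without resistant rust distal replicates 1 and 2, 14 without resistant mock distal replicate 2, 73 without susceptible rust distal replicate 3 and 11 without susceptible mock distal replicate 2.

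Across lines, rust acted differently on the leaf parts for PsbP, whose change was lower in distal than basal leaf by -0.62 ± 0.15 (adjusted p = 0.0481), and for TSA (-0.48, adjusted p = 0.0436). LOC778410 (2.25 ± 0.42, adjusted p = 0.0195), LOC543448 (1.21) and LOC780589 (0.91) changed more upward in distal leaf, and LOC543355 (-0.87) and LOC543436 (-1.15) more downward. The interaction covered 197 probe sets, 79 higher and 118 lower (adjusted p), against 4927 at an unadjusted p of 0.05. The count was 22 without a trend, 42 without a filter, 298 after quantile normalization, 337 in a fit of these groups alone and 348 with the top 40% of probe sets. It was higher still with replicate blocks, by number or of leaf parts, as listed with the processing below. It also hung on single arrays, and PsbP kept its call in 6 and TSA in 10 of 24 such fits. It was 123, 62 and 40 without resistant rust basal replicates 1 to 3, 53, 34 and 128 without resistant rust distal replicates 1 to 3, and 123 and 32 without resistant mock basal replicates 1 and 2. Without resistant mock distal replicates 1 to 3 it was 32, 108 and 20, without susceptible rust basal replicates 2 and 3 it was 31 and 43, and without susceptible rust distal replicates 1 and 3 it was 75 and 361. Without susceptible mock basal replicates 1 to 3 it was 49, 39 and 388, and without susceptible mock distal replicates 1 and 2 it was 44 and 33.

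Distal leaf carried more LOC542799 than basal leaf in mock-inoculated Jupateco, by 3.23 ± 0.36 averaged over the lines (adjusted p = 4.05e-06, n = 6 against 6), and more LEA1 (1.88 ± 0.39, adjusted p = 0.0226). In the susceptible line they read 5.66 and 6.26 in distal against 5.12 and 6.0 in basal leaf. LOC543167 (0.66) and LOC780592 (0.23) were higher and tubb2 was lower (-0.79 ± 0.17, adjusted p = 0.0346, kept in 6 of 13 fits without 1 array). Unnamed Ta_13337_2_S1_x_at (2.89) and Ta_13337_2_S1_at (2.79) were highest, and Ta_28750_2_A1_x_at (-3.80) and Ta_28750_1_S1_x_at (-3.24) lowest. In all, 138 probe sets differed, 79 higher and 59 lower (limma, adjusted p), or 511 (304 higher and 207 lower) with a replicate block pairing the leaf parts by number. The unpaired count was 89 without resistant distal replicate 2, 85 without susceptible basal replicate 1, 91 without susceptible distal replicate 2, and 10 in a fit of these groups alone. For LOC542799 the distal excess was larger with Lr34 by 5.38 ± 0.71 (adjusted p = 0.000916). It was 1 of 8 probe sets with such an interaction, 5 higher and 3 lower, or 6 and 2 after quantile normalization, 23 with the replicate block, 3 with the top 40% of probe sets and 1 in a fit of these groups alone. Without resistant distal replicate 1 the 8 became 14, without susceptible distal replicate 2 they became 18, and without susceptible distal replicate 3 they became 4.

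In mock-inoculated Thatcher, distal leaf carried more LOC542799 (4.34 ± 0.36, adjusted p = 3.63e-10, n = 6 against 6), LOC778410 (3.37, adjusted p = 1.21e-09), LOC542888 (3.33) and LEA1 (2.85, adjusted p = 5.18e-06) than basal leaf. These averages over the lines came mostly from the resistant one for LOC542799, LOC542888 and LEA1. In susceptible leaf they read 5.64, 6.90 and 5.46 in the distal against 4.8, 5.91 and 5.00 in the basal part. The cap-binding factor eIF4E (-0.49, adjusted p = 0.000436), the prolyl isomerase FKBP70 (-0.74 ± 0.12, adjusted p = 9.31e-05) and the tubulins TUBA (-0.46, adjusted p = 0.000637) and tubb2 (-0.61, adjusted p = 0.0176) were lower. AGP-S, the small subunit of ADP-glucose pyrophosphorylase (-0.35, adjusted p = 0.000247), ALP (-0.31) and TEF1 (-0.20) were lower too. PEAMT1 (0.77, adjusted p = 0.0107), 6-FEH (0.79, adjusted p = 0.00882) and GSTZ1 (0.27) were higher. AGA.1 was higher by 1.06 on Ta_23665_1_A1_at, whereas its brighter Ta_23665_1_S1_at read -0.10. For rbcl, TaAffx_128896_17_S1_s_at was higher by 1.51 ± 0.16 (adjusted p = 9.98e-08) and the brightest probe set was not (0.12). Further LOC genes were higher, LOC606363 (2.76), LOC100125736 (2.06), LOC606323 (1.91), LOC543448 (1.80), LOC542778 (1.63) and LOC543396 (1.49), or lower, LOC543287 (-1.86), LOC543090 (-1.19), LOC542826 (-1.03), LOC543216 (-0.94), LOC100037531 (-0.86), LOC100037645 (-0.84), LOC543461 (-0.76), LOC543268 (-0.72) and LOC543332 (-0.71). In all, 5298 probe sets differed, 2881 higher and 2417 lower (limma, adjusted p), and 10268 at an unadjusted p of 0.05. Unnamed TaAffx_143997_1_S1_s_at (6.34) and TaAffx_143996_1_S1_s_at (4.70) were highest and Ta_22564_2_S1_x_at (-2.89) and Ta_22564_2_S1_a_at (-2.54) lowest.

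The difference between the Thatcher lines depended on the part of the leaf. In mock leaves the effect was more positive in distal than basal leaf for LOC542799 (7.0 ± 0.71, adjusted p = 4.35e-07), LEA1 (4.78, adjusted p = 0.000481), LOC542888 (4.70, adjusted p = 3.54e-05), LOC543150 (3.74) and LOC542781 (3.45). The term was also positive for PEAMT1 (1.93 ± 0.41, adjusted p = 0.0122), which was lower with Lr34 in mock basal leaf. The interaction took in 249 probe sets, 245 higher and 4 lower (adjusted p). A replicate block of leaf parts gave a higher count, listed with the processing below, but the numbers were not taken as pairs in Thatcher. In rust-inoculated leaves LOC542799 (7.21, adjusted p = 6.28e-08), LOC542888 (5.82), LEA1 (5.25), LOC543150 (3.90) and LOC778383 (3.50) led the positive terms. Negative terms included wcH2B-8 on Ta_7378_21_S1_at (-2.48 ± 0.61, adjusted p = 0.0128), lgul on Ta_8554_1_S1_at (-1.12, adjusted p = 0.0323), Pgk-1 (-0.84, adjusted p = 0.0166), Trx-M (-0.63, adjusted p = 0.0224), AGP-S (-0.50, adjusted p = 0.0142), LOC542794 (-1.10), LOC542880 (-1.07) and LOC606324 (-1.06). There 1891 probe sets differed, 1166 higher and 725 lower, and 1071 without resistant rust distal replicate 2, 1126 without susceptible rust basal replicate 1 and 1177 without susceptible rust distal replicate 2. The replicate block of leaf parts raised this count too.

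Between the backgrounds, the Lr34 effect in mock distal leaf was higher in both for LOC542799, LEA1, LOC542888, LOC542781 and LOC780599 among named genes. In total 41 probe sets were higher with Lr34 in both, where 2.96 would be shared if the calls were independent, and 0 were lower in both (0.393 expected). Of the 41, 39 were also higher with Lr34 in rust-inoculated distal leaf. Over all probe sets the effects correlated with r = 0.107 in distal (0.061 without a filter) and r = 0.008 in basal leaf, where 1 probe set was higher in both (0.068 expected). In basal leaf the Lr34 effect in Jupateco minus that in Thatcher was 5.78 for LOC542869 (adjusted p = 1.58e-11) and positive for LOC780602 (3.59), LOC542908 (2.42), LOC606366 (1.38) and LOC542778 (1.14), all lower with Lr34 in Thatcher. LOC100125710 (-1.92) and LOC100037524 (-0.85) had negative terms, and 136 probe sets differed, 94 higher and 42 lower (interaction term, adjusted p), or 74 in a fit of these groups alone. In distal leaf GLU1A (-3.54, adjusted p = 0.00279), LOC543338 (-1.98), LOC543018 (-1.94), LOC100125710 (-1.53) and LOC606347 (-1.11) had negative terms. LOC542869 (6.35, adjusted p = 1.67e-12), LOC100125708 (4.96, adjusted p = 0.0446), LOC543438 (4.82), LOC780602 (2.30) and LOC542908 (2.30) had positive terms. Only 2 of these 10 named genes kept their call in every fit without 1 array, LOC100125708 in 3 of 13. There 301 probe sets differed, 115 higher and 186 lower, with 597 without Jupateco susceptible distal replicate 2 and 154 in a fit of these groups alone.

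**Figure D3:**
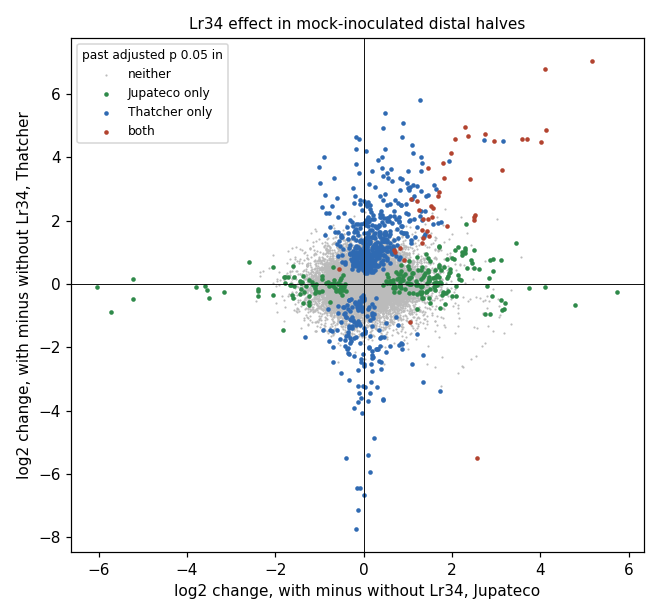
Log2 change with Lr34 in mock distal leaf of Jupateco and Thatcher, 1 point per probe set.

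The rust response was shared by the Thatcher lines, measured on separate arrays. In distal leaf the log2 changes correlated with r = 0.618, 1338 probe sets were higher in both (184 expected if calls were independent) and 2151 lower in both (432 expected). In basal leaf r was 0.432, with 128 higher (10.1 expected) and 180 lower (21.4 expected) in both. Across the 4 rust comparisons 93 probe sets rose throughout, among them LOC542890, LOC543101, LOC543297 and LOC778397. A further 142 fell throughout, among them LOC100037539, LOC542855, LOC542880, LOC606346 and LOC778422. XIP-I and DMAS1 rose in 3 of the 4 comparisons, and LTP3, PEAMT1, lgul and RPL9 fell in 3 of the 4. None of them was called in resistant basal leaf, but no difference between the lines was called for them either. LTP3 read -0.82 there (adjusted p = 0.0885) and fell when adjusted over its list alone.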

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

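What follows are tests of a difference between effects, made as interaction terms of the same model. They were planned, except for the fits without 1 array of susceptible rust distal leaf in comparisons that do not use its group, and for the exchanges within Jupateco leaves, which were chosen only after the result was seen.

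Few probe sets were called as responding differently to rust in the Thatcher lines: 13 in basal leaf, LOC606366 among them, and 27 in distal leaf, none of them named. In 100 permutations of the residuals from the model without the interaction, no other gave as many, with highest counts of 3 and 6, so chance could be excluded for both (1 of 100 each, the real one). Permutations in this part did not keep leaf pairs, except where said. The distal share of higher calls was not stable, 18 of 27 as scaled by the authors and 17 of 33 after quantile normalization.

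The rust response differed between leaf parts for 197 probe sets, among them PsbP and TSA, whose changes were lower in distal leaf, and LOC778410, whose change was higher. The highest count in other permutations was 1, which excludes chance (1 of 100). Even so, leaving out 1 array gave 20 to 388, and other processing gave 22 without a trend, 42 without a filter and 348 with the top 40% of probe sets. Replicate blocks, by number or of leaf parts, gave higher counts still, listed with the processing below. The number itself is thus loose.

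The Lr34 effect differed between leaf parts for 8 probe sets in Jupateco, led by LOC542799, of which 5 were higher (6 of 8 after quantile normalization). Permutations that broke up the leaf pairs did not exclude chance: 24 of 100 reached that count, and the highest gave 2372. A permutation calling so many more than the real labels points to a structure of the samples. With the pairs kept and fitted as blocks 23 differed, and exchanges of residuals within the 6 leaves excluded chance (1 of 32, highest other 10). In Thatcher 249 probe sets differed in mock leaf, LOC542799, LEA1, LOC542888 and PEAMT1 among them, with 14 as the highest other count (1 of 100), which excludes chance. In rust-inoculated Thatcher 1891 differed, including LOC542799, wcH2B-8 and Trx-M. There 2 of 100 gave as many, the real one among them, and the highest gave 2013. That share is under 0.05, but chance is not called excluded. The residuals were pooled over arrays whose root mean square deviations from the group mean were 0.298 to 0.438. The permuted residuals still held the real interaction, so the near match cannot tell a structure of the samples from the interaction itself.

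The Lr34 effect differed between the backgrounds for 136 probe sets in basal leaf, with LOC542869 first, and for 301 in distal leaf, with LOC542869 and GLU1A. For basal leaf the highest other count was 11 (1 of 100) and chance could be excluded. In distal leaf 2 of 100 gave as many, with 396 the highest. That share is under 0.05, but chance is not called excluded. The residuals were pooled over arrays of unlike spread, with root mean square deviations from the group mean of 0.319 to 0.452. Here too the permuted residuals held the real interaction, so the higher count cannot tell a structure of the samples from the interaction. Without Jupateco susceptible distal replicate 2, 597 probe sets were called.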

How the results depend on the processing

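Signal over background limits small signals: with 16 added, folds of dim probe sets are too low, and with 1 array per leaf sample and 3 per group small changes are missed. Values are counts of called probe sets unless named, and the cause was not tested. Over all comparisons the named genes kept their call in 2409 of 2619 alternative fits and in 1971 of 2569 fits without 1 array, and none reversed.

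With 64 added, Lr34 by rust in distal leaf gave 57, and agreement of the rust effect 0.511 in basal and 0.689 in distal leaf; with 1 added, agreement was 0.373 and 0.561. Without a filter, rust by leaf part gave 42 and agreement was 0.061 for Lr34 in distal leaf and 0.279 and 0.453 for rust in basal and distal leaf. With the top 40% of probe sets, Lr34 by rust in distal leaf gave 42, rust by leaf part 348, Lr34 by leaf part in Jupateco 3, and agreement for rust 0.580 and 0.745. Quantile normalization gave 21 for Lr34 by rust in basal leaf and 298 for rust by leaf part, and no trend gave 22 for the latter.

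A replicate block by number gave 23 for Lr34 by rust in basal leaf and 384 for rust by leaf part. A replicate block of leaf parts gave 862 for rust by leaf part, 511 for distal against basal Jupateco, 23, 407 and 3112 for Lr34 by leaf part in Jupateco, mock Thatcher and rust-inoculated Thatcher. Of 18 pairs 11 correlated over 0.1 and 16 best with their own number. Fits of the compared groups alone gave 9 and 12 for Lr34 in Jupateco basal and distal leaf, 145 in Thatcher mock basal leaf, 27 for Lr34 by rust in basal leaf, 337 for rust by leaf part, 10 for distal against basal Jupateco, 1 for Lr34 by leaf part there, and 74 and 154 for Lr34 by background in basal and distal leaf.

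Gene groups lost calls. With an estimated correlation, photosynthesis genes gave 0.379 (Lr34, Jupateco distal), 0.305 (Lr34, rust basal), and by rust 0.611, 0.0968, 0.43 and 0.2 in resistant basal and distal and susceptible basal and distal leaf. Redox genes gave 0.12, 0.0968 and 0.0995, starch genes 0.0665 and 0.105, tubulins 0.466. Over all probe sets photosynthesis gave 0.0632 (Lr34, rust basal) and 0.0755 (rust, resistant basal), and starch 0.125 and 0.275. Quantile normalization gave 0.605 and 0.283 for photosynthesis, 0.103 for redox and 0.0636 for starch genes.

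Leaving out 1 array gave these ranges. Lr34: Jupateco basal 43 to 65, distal 145 to 1161; Thatcher mock basal 186 to 324, distal 462 to 754; rust basal 154 to 465, distal 1664 to 3587. Rust: resistant basal 224 to 982, distal 4343 to 6783, susceptible basal 836 to 3224, distal 3803 to 6282. Leaf part: Jupateco 85 to 196, Thatcher 3778 to 5760, rust by leaf part 20 to 388. Lr34 by rust: basal 7 to 17, distal 8 to 73. Lr34 by leaf part: Jupateco 4 to 18, Thatcher mock 204 to 266, rust 1071 to 2294. Lr34 by background: basal 100 to 160, distal 205 to 597. Agreement of Lr34: basal -0.0148 to 0.0245, distal 0.0734 to 0.139. Agreement of rust: basal 0.368 to 0.473, distal 0.561 to 0.637.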

Other observations

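Chosen only after the result was seen were the overlaps of the Lr34 effect between mock and rust-inoculated Thatcher and of the Jupateco Lr34 effect with the rust effect, the swaps within Jupateco leaves, the form of the splits for shared calls and, for the 3 patterns at the end, the tests of signal level, scaling, leaf tip, mislabelling and a difference shared by the backgrounds.

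PEAMT1, a methyltransferase on the way to choline, stood at different levels in the backgrounds. In Jupateco its mean log2 signal was 14.40 to 14.80 over the 4 groups, against 10.17 to 12.21 in Thatcher (n = 3 arrays each). Rust lowered it in distal leaf of both Thatcher lines and in susceptible basal leaf. In resistant basal leaf it was already low when mock inoculated (10.47 ± 0.70, SD). No comparison between the backgrounds as such was tested.

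LOC543233 (no function given in the tables used here) averaged 8.07 ± 1.03 (SD) in basal and 10.23 ± 0.80 in distal leaf of rust-inoculated resistant Thatcher, against 4.61 ± 0.75 and 6.65 ± 1.14 in the susceptible line. Mock leaves read 5.05 and 7.44 in the resistant and 5.77 and 8.07 in the susceptible line. A difference in rust response was not called (4.18 ± 1.19, adjusted p = 0.244 in basal and 4.20 ± 1.19, adjusted p = 0.227 in distal leaf). LOC100125708 ended at 14.05 and 14.09 in rust-inoculated distal leaf of the resistant and susceptible line, having started at 8.66 and 11.47. A difference between the lines in this distal rust response was not called. Its rise in susceptible distal leaf kept its call in only 1 of 6 fits without 1 array. With Lr34, 449 probe sets were higher in both mock and rust-inoculated Thatcher distal leaf (25.5 expected if independent). In basal leaf 85 were lower in both (1.47 expected).

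Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For the Lr34 effect the real labels gave 58 in Jupateco basal leaf (highest other 10), 300 and 690 in Thatcher mock basal and distal leaf (2 and 2), and 406 and 3166 in rust-inoculated basal and distal leaf (2 and 4). For rust they gave 787 and 6427 in resistant basal and distal leaf (1 and 3) and 2848 and 6739 in susceptible leaf (1 and 4). Jupateco distal leaf differed: 294 against 629 for resistant replicates 1 and 2 with susceptible replicate 2, which points to a structure of the samples. For distal against basal Thatcher leaf chance could be excluded (5298, 1 of 100, highest other 1068). In Jupateco, splits that broke up the leaf pairs did not exclude it (138, 18 of 100 as many, highest other 1628, which points to a structure of the samples). With the pairs kept and fitted as blocks, swaps of basal and distal within the 6 leaves did exclude it (511, 1 of 32, highest other 60).

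Splits of 3 and 3 were also too few for the gene groups, where the smallest other camera p is given beside the real one, both unadjusted. Photosynthesis and chloroplast genes gave 0.00261 against 0.000767 in Jupateco distal leaf (3 of 10 as small), 0.00207 against 5.69e-06 in rust-inoculated Thatcher basal leaf (2), and after rust 0.0136 against 0.000253 in resistant basal (3), 3.97e-08 against 1.24e-05 in resistant distal (1), 0.00092 against 4.94e-08 in susceptible basal (4) and 6.09e-06 against 1.02e-06 in susceptible distal leaf (2). Redox genes gave 0.016 against 0.082 (1), 0.0117 against 0.00841 (3) and 0.00426 against 0.0161 (1) in rust-inoculated basal leaf by Lr34 and in resistant and susceptible distal leaf by rust. Starch and sugar genes gave 0.00492 against 0.0213 (1) in mock distal and 0.00908 against 0.0419 (1) in rust-inoculated basal Thatcher leaf by Lr34, and tubulins 0.00924 against 2.15e-05 (4) in resistant basal leaf by rust.

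For the agreement of the Lr34 effect between backgrounds, chance could not be excluded in basal (r = 0.008, 93 of 100 as high, highest other 0.182) or distal leaf (r = 0.107, 8 of 100, highest other 0.183). For the 41 probe sets raised in both distal comparisons, only the 10 splits of the Jupateco arrays were used, since other Thatcher splits called at most 2. They are too few for a share under 0.05 (highest other 16). Agreement of the rust effect was beyond chance in distal leaf (0.618, 1 of 100, highest other 0.458). In basal leaf the real labels gave the highest r too (0.432, 1 of 100), but by a small margin. Another pair of splits reached 0.422, and leaving out 1 array lowered the real r to as little as 0.368.

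The 207 probe sets raised with Lr34 in mock Jupateco distal leaf, LOC542799 and LOC606323 among them, were as a set also higher after rust in susceptible Thatcher distal leaf. Their median change was 0.44 there and 0.39 in resistant distal leaf, above every one of 10000 sets matched on signal (highest 0.068 and 0.059), and 70 were called higher in the susceptible line (15.5 expected). Signal level is thus excluded, as is the authors' scaling (98 shared after quantile normalization, 21.5 expected). A leaf-tip pattern would need higher signals in distal than in basal leaf. In mock susceptible Thatcher the set's median distal minus basal change was -0.0287 (median absolute deviation 0.4401, 49.3% positive). That median lay at percentile 1.38 of the 10000 matched sets, so the set as a whole was not higher in distal leaf of that line. A leaf-tip pattern stays open, because the members went both ways. That line also lacks Lr34, so a pattern that appears only with Lr34 could not show there. RNA quality, untested for this set, is neither excluded nor shown. The glucose-6-phosphate dehydrogenase 3′ to 5′ log2 ratio was higher by 0.58 with Lr34 in Jupateco distal leaf. After rust in susceptible distal leaf it was higher by 0.85. The sucrose synthase ratio read -0.21 and 1.22 in these comparisons. For the 87 calls in the same direction the 10 splits of the Jupateco arrays are too few for a share under 0.05. The highest other gave 304 (2 of 10 as many), which points to a structure of the samples. Without resistant distal replicates 1 to 3 the 70 became 45, 47 and 41 (12.6, 9.81 and 8.31 expected). Without susceptible distal replicates 1 to 3 they became 29, 429 and 27 (8.31, 66.2 and 7.94 expected).

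Replicate 2 of rust-inoculated susceptible Thatcher distal leaf lay at a median distance of 0.321 from its replicates, with 1 array of another group, Jupateco susceptible distal replicate 2, higher at 0.324. A mislabelled array is excluded, since its own group ranked 1 of 12 by correlation (0.954, the next 0.941). Its deviation did not follow the rust effect in distal leaf of the resistant line (r = -0.0647), which argues against a different strength of that response. A response particular to the susceptible line was not tested, so it is not excluded. Lower RNA quality fits, with a sucrose synthase 3′ to 5′ log2 ratio of 4.8 against 2.63 to 3.97 on the other arrays. Noise of dim probe sets stays open, because the array ranked 4 of 36 over the brightest probe sets (0.217, highest other 0.236) and only 2 over all, which hardly tests it.

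In Thatcher 84 probe sets differed with Lr34 in all 4 comparisons, 29 higher and 55 lower, with a median size of 2.12 log2. LOC542869, LOC542908 and LOC780602 were lower and LOC100037524 and LOC100125710 higher. In both Jupateco leaf parts 44 probe sets differed (21 higher, 23 lower), and 0 did so the same way in all 4 Thatcher comparisons. That cannot exclude a difference shared by the resistant lines of both backgrounds for the 84 as a set. A call was needed in every comparison, and Jupateco basal leaf gave only 58. For the named genes among the 84, the Lr34 effect in mock basal leaf did differ between the backgrounds, as given above. Lost hybridisation in one line, as sequence differences could cause, can be neither excluded nor shown: in 35.7% of the 84 the lower line fell under the lowest mean signal tested.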
